A study of Mus musculus with 24 samples.

How the data were processed

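RNA was measured in βTC3 cells, a mouse insulinoma line derived from the Rip-Tag2 model of pancreatic neuroendocrine tumours. Per the labels, the cells carried the plasmid PB-31 as a control, PB-31 with the miR-23b cluster, or PB-31 with miR-137, each inducible by doxycycline (DOX). Cells were plated in triplicate and cultured for 7 d in plain medium (no DOX), for 7 d with DOX at 2 µg/ml (7 d DOX), or for 7 d with DOX and another 7 d without it (DOX withdrawn). The control line had the first 2 conditions and the miRNA lines all 3, which gave 8 groups of 3 libraries and 24 libraries in all. Libraries were prepared with a stranded polyA kit. Groups and replicate numbers were taken from the sample labels. The labels gave no untreated culture kept as long as the withdrawn cultures, no withdrawn control culture, and no date, plate or run.

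The deposited files per sample hold raw read counts per gene, without normalization, for 46517 gene entries, of which 46005 had a symbol in GENCODE M21. The submitters' processing notes name cutadapt 1.3, STAR 2.4.0g, HTSeq 0.6.1, RSEM 1.2.19 and featureCounts with the builds GRCm38 and mm10. Which tool made each deposited table, and the alignment settings, are not given in the sources used here. A deposited table of counts for the whole series held the same counts as the files per sample, with 0 differing values. A further table, scaled by the authors per library with a length term, was read as TPM because its columns summed to between 999999.3 and 1000001.3. It lists 5 genes with over 1000 counts at 0, among them Mir23b, Mir27b and Mir24-1, so it was used as an alternative only.

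Each library held 15759849 to 24144737 reads counted in genes. Reads outside any gene made up 9.62% to 12.1% of all reads listed, and reads aligned to more than 1 place 25.4% to 27.7%. The latter were not counted in genes, so values of genes with near-identical copies, such as Ins1, Hspa1a, Pcdhb18 and Serpina1a, are less certain. A count of 0 over the 3 libraries of a group allowed a level of up to 3 counts over their total, which covers counting error only. Levels of the miRNA loci and their host genes are unadjusted CPM (counts scaled to all gene counts of the library). Levels of all other genes are CPM of TMM-scaled library sizes. Reads from an inserted miRNA copy and from the gene's own locus cannot be told apart in these counts, and polyA libraries do not measure mature miRNAs.

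Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults, which left 14866 genes, libraries were scaled by TMM, and all 24 libraries were fitted in 1 model with 8 group means and trended dispersion. The common coefficient of biological variation was 3.00%. Comparisons were tested with edgeR's quasi-likelihood F test, and genes counted as changed at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. The 12 comparisons were 7 d DOX against no DOX in each line, the 3 differences between these responses, withdrawal against 7 d DOX and against no DOX in each miRNA line, and each miRNA line against the control line without DOX. Errors of log2 fold changes (SE) are the size of the log2 fold change divided by the square root of the test's F statistic. They are too small for large changes where 1 group has few counts, such as those of Mir23b, Phlda3 and Ak4. Errors of levels are standard deviations (SD). Both have n = 3 libraries per group. The p-values measure the spread between the 3 libraries of a group. Cells were plated in triplicate, and whether the libraries come from separate passages or experiments is not given in the sources used here, so this spread may be technical. Logged levels used a prior count of 2, and principal components were taken from these values.

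In the 3 comparisons of 7 d DOX with no DOX, up to 10 rising and 10 falling genes were named, by size of fold change. They had to pass the test, reach 5 CPM in the higher group, show no overlap between the groups and carry a symbol other than a clone, pseudogene or predicted gene name. In the miRNA lines they also had to differ from the control line's response in the same direction. Other comparisons named up to 5 genes in each direction. For differences between responses, overlap was judged on each 7 d DOX library minus the mean of its line without DOX, and the 5 CPM in the highest of the 4 groups. The miRNA loci and their hosts were named whatever their values. Some of the genes selected are not reported here. Each gene named by size of change thus had its 3 libraries of 1 group all above or all below those of the other. In a comparison of 2 groups chance alone gives this in 10% of genes. For differences between responses the share is higher, since the 3 libraries of a line have the same mean subtracted.

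A further 24 lists of genes were written from general knowledge of gene function. They cover beta cell identity and insulin secretion, islet progenitors and dedifferentiation, other islet and gut hormones, G1/S and G2/M cell cycle genes, p53 targets and CDK inhibitors, mesenchymal and matrix genes, and epithelial genes. Others hold ER stress, ATF4 and mitochondrial stress, mitochondrially encoded, nuclear oxidative phosphorylation, glycolysis (with hypoxia-responsive genes), cholesterol synthesis, interferon response, and TGF-beta, activin and BMP genes. The rest are neuronal and exocytosis genes, reported targets of miR-137, reported targets of miR-23b, miR-27b and miR-24, immediate early and heat shock genes, and markers of fibroblasts, leukocytes, endothelium and exocrine pancreas. Members passing the test were counted over all genes and adjusted over the list alone. The 21 lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment within a comparison. The test was repeated with an estimated correlation, and with fry, which asks only whether members move in 1 direction. Up to 4 members with the smallest adjusted p were named.

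Sites were 7-base matches to positions 2 to 8 of miR-137, miR-23b-3p, miR-27b-3p and miR-24-3p in the longest annotated 3' UTR of each gene (GENCODE M21), which covered 13000 of the tested genes. The log2 fold change was regressed on the presence of a site, with UTR length and GC share as covariates. The coefficient was ranked among all other 7-base words found in 0.5 to 2 times as many genes. The rank is a description, since genes are not independent replicates.

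The test, lists, comparisons, naming rule and most alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0, size factors in place of TMM, no filter on low counts, a fit of only the groups compared, replicate number as a block, a fold of at least 2, and leaving out each library. Site results were also computed with 8-base sites, without covariates, from genes at 5 CPM or more, and from the line's own response. limma on log2(TPM + 1) was chosen after seeing the data. The test was tried on simulated data in 2 comparisons: it called 77% of genes given a 1.5-fold change and 88% given a 2-fold change in a comparison of 2 groups, and 67% and 80% in a difference between responses. The simulated change given to 1 list was called by camera in that list alone. Genes were drawn independently there, so the simulation cannot show false calls that arise from correlation between list members. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Raw reads, splicing and mature miRNAs were not analysed here.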

Results

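PolyA RNA was sequenced from βTC3 insulinoma cells in 8 groups of 3 libraries, with 15759849 to 24144737 gene counts per library. The question addressed is how the transcriptome responds when DOX switches on miR-137 or the miR-23b cluster, which encodes miR-23b, miR-27b and miR-24, and when DOX is removed again. The first principal component held 32.3% of the variance and placed the no DOX libraries of all 3 lines together, at scores of -26.4 to -21.1. The control and miR-137 lines with 7 d DOX and both withdrawn lines lay between 5.61 and 11.7. The miR-23b line with 7 d DOX lay apart, at 35.6 to 36.8.

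**Figure D1:**
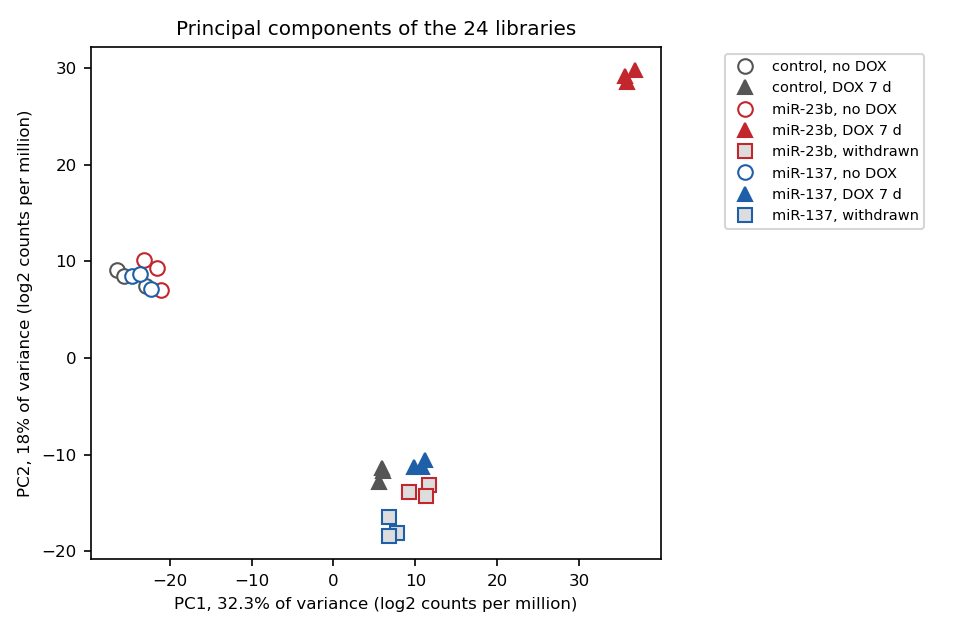
First 2 principal components of log2 CPM, with axes as scores and each point 1 library, coloured by group (3 libraries each). The miR-23b line with DOX lies at 35.6 to 36.8 on the first component and the no DOX libraries of all lines below -21.

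The induced loci were read first. In GRCm38 the cluster lies on chromosome 13, plus strand, inside the host gene 2010111I01Rik (ENSMUSG00000021458, 62964893 to 63326096). Mir23b (ENSMUSG00000065599, 63300484 to 63300557) stood at 0.154 ± 0.0839 unadjusted CPM (SD, n = 3) in the miR-23b line without DOX, 53.2 ± 3.17 with 7 d DOX and 0.0386 ± 0.0339 after withdrawal. Mir27b (ENSMUSG00000065475, 63300712 to 63300784) went from 0.481 to 85.5 ± 5.35 and back to 0.111. Mir24-1 (ENSMUSG00000105904, 63301208 to 63301275) went from 0.641 to 104 ± 8.50 and back to 0.211. Their rises with DOX were 302-fold, 166-fold and 156-fold (log2 SE 0.16, 0.13 and 0.13). These folds are less certain than the SE imply, as the no DOX libraries held only 9, 27 and 35 counts in all. The no DOX levels of these 3 loci in the miR-23b line exceeded all group means of the other lines, which reached at most 0.118. Mir3074-1, on the minus strand at 63301199 to 63301283, stood at 0.743, 0.479 and 0.205 in the 3 conditions, and the host gene at 15.5, 18.5 and 18.0.

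Mir137 (ENSMUSG00000065569, chromosome 3, 118433857 to 118433929, plus strand) had 0 counts in every library. It lies inside another transcript on the same strand, and read assignment there was not tested, so the 0 sets no limit on its level. That transcript, Gm26871 (ENSMUSG00000097311, 118430324 to 118530022, plus strand), rose in that line from 4.35 ± 0.389 to 123 ± 3.11 unadjusted CPM (log2 fold change 4.81, SE 0.08, n = 3). After withdrawal it stood at 2.58 ± 0.784. Gm26871 was also called higher in the miR-23b line, from 2.17 to 5.38 (log2 fold change 1.28, SE 0.16), and stood at 3.20 and 3.59 in the control line.

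**Figure D2:**
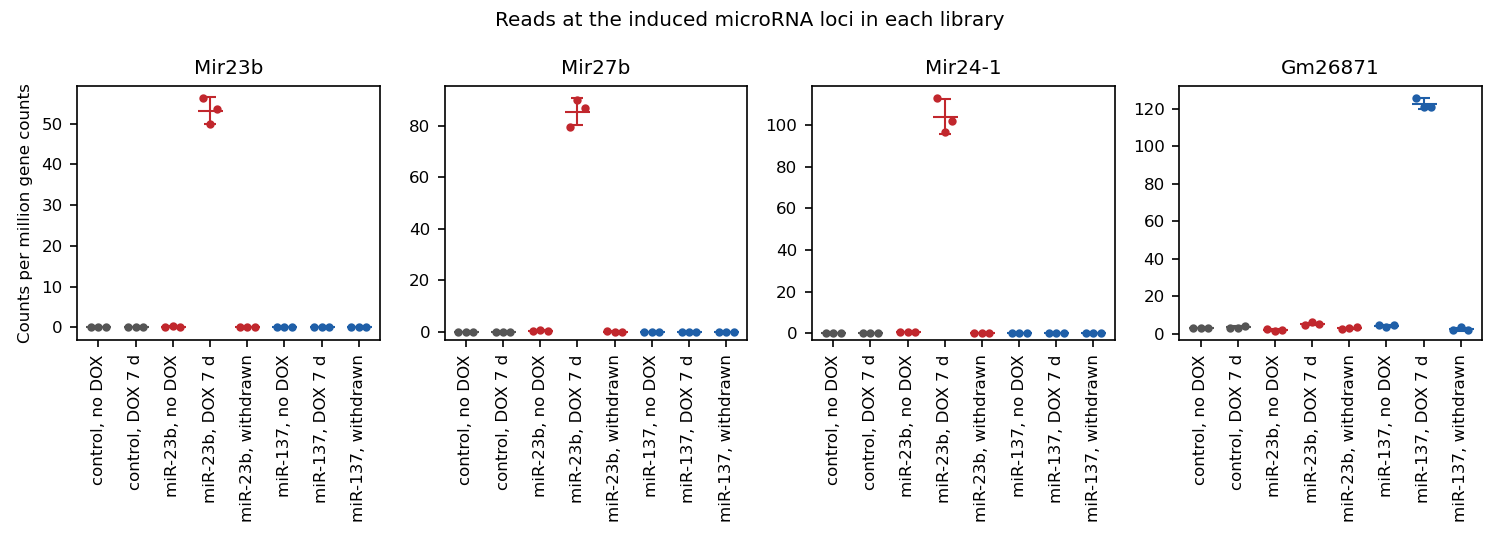
CPM of gene counts for the induced loci in each of the 8 groups, with points as libraries (n = 3) and bars as group means and SD. Mir23b reaches 53.2 in the miR-23b line with DOX and Gm26871 reaches 123 in the miR-137 line with DOX.

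In control cells, the activity-induced transcription factor genes Fosb (log2 fold change -3.10, SE 0.11, n = 3), Egr2 (-2.58, SE 0.15), Npas4 (-2.22, SE 0.10), Nr4a1 (-2.12, SE 0.08) and Fos (-1.86, SE 0.08) were lower with DOX than without. DOX cannot be told apart here from a batch shared by the no DOX cultures, since the labels give no date, plate or run. The same limit applies to each comparison of DOX or withdrawn cultures with no DOX cultures. The mitochondrial gene Chchd10 fell by 1.68 on the log2 scale (SE 0.10). Peptide precursor genes rose, namely prodynorphin (Pdyn, 1.94, SE 0.08), secretin (Sct, 1.69, SE 0.08) and proglucagon (Gcg, 1.38, SE 0.09). The lectin gene Mgl2 rose by 2.62 (SE 0.16), to 7.80 CPM. Of 14866 genes, 5624 (37.8%) passed edgeR's quasi-likelihood test, 2753 higher and 2871 lower (49.0% higher, and 48.9% on the TPM scale), with a median size of 0.264 on the log2 scale. The control libraries with DOX also showed more genes with at least 1 count, 20898 to 21066 against at most 20336 in the other 21 libraries. Each difference from the control line's response includes these libraries.

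Cholesterol synthesis genes, which sterols repress through SREBP2, moved as a block in control cells. Of 25 members 24 were lower and 0 higher (24 lower adjusted over the list alone), among them Insig1 (-1.52) and Msmo1 (-1.09), with a camera adjusted p of 1.31e-63. Of 21 immediate early and heat shock genes 11 were lower and 2 higher (11 and 2 adjusted over the list alone, camera adjusted p 7.04e-13). Of 36 ATF4 and mitochondrial stress genes, which respond to amino acid shortage, 27 were lower and 1 higher (28 and 1 adjusted over the list alone, 5.17e-12), such as Chac1 (-0.87) and Atf4 (-0.45). With an estimated correlation these 3 calls held, at adjusted p of 4.49e-05, 0.000528 and 0.0104, and the other 7 of the 10 camera calls among 21 lists did not.

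The proliferation lists were among those 7. G2/M genes had 25 of 39 members higher and 1 lower (26 and 1 adjusted over the list alone), with Ccnf up by 0.41, at a camera adjusted p of 2.03e-07 but adjusted p = 0.178 with an estimated correlation. G1/S genes had 20 of 36 higher and 5 lower (21 and 6 adjusted over the list alone), with Rrm2 at 0.49 and Chaf1b at -0.36, camera adjusted p 0.0039 but adjusted p = 0.229 with an estimated correlation. ER stress genes had 13 of 21 higher and 1 lower (13 and 1 adjusted over the list alone), with the chaperone gene Pdia4 at 0.55 and Herpud1 at -0.54, camera adjusted p 0.000201 but adjusted p = 0.206 with an estimated correlation. Hormone genes had 5 of 10 higher and 0 lower (5 and 0 adjusted over the list alone), including Cck at 1.12, camera adjusted p 0.00128 but adjusted p = 0.0563 with an estimated correlation. Glycolysis genes had 18 of 27 lower and 3 higher (18 and 4 adjusted over the list alone), with Aldoc at -0.94 and Pfkfb3 at 1.08, camera adjusted p 0.000503 but adjusted p = 0.487 with an estimated correlation.

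Some respiratory chain genes fell in control cells with DOX, an antibiotic of a class that inhibits mitochondrial translation. Of 7 mitochondrially encoded genes 5 were lower and 0 higher (5 and 0 adjusted over the list alone), with mt-Nd1 at -0.60, camera adjusted p 0.00537 but adjusted p = 0.371 with an estimated correlation. Of 48 nuclear encoded genes 20 were lower and 1 higher (20 and 1 adjusted over the list alone), with Ndufa6 at -0.35, camera adjusted p 0.00852 but adjusted p = 0.49 with an estimated correlation. Markers of other cell types had few tested members. The fibroblast list had 1, Col1a1, called higher with DOX (log2 fold change 0.50), and the leukocyte and endothelial lists had 2 each, too few to test. Of the 2 endothelial genes Pecam1 was called higher (1.87, SE 0.54), at 0.539 CPM with DOX, and of the 2 leukocyte genes 0 were called. Of 3 exocrine genes 1 was higher and 0 were lower (1 and 0 adjusted over the list alone), camera adjusted p 0.283, while fry called the list higher at 3.81e-05.

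In the miR-23b line, Ak4, a mitochondrial adenylate kinase, fell with 7 d DOX from 37.2 ± 2.19 to 0.322 ± 0.238 CPM (log2 fold change -6.79, SE 0.27, n = 3). Ldha, which makes lactate from pyruvate, fell from 633 ± 64.6 to 46.5 ± 1.00 CPM (-3.77, SE 0.14). Egr2 (-3.38, SE 0.17) and Insig1, which retains SREBP in the ER (-2.83, SE 0.05), fell further than in control cells. The p53 target Phlda3, a repressor of AKT, rose from 0.682 ± 0.103 to 8.62 ± 0.353 CPM (3.65, SE 0.18). Sct (2.51, SE 0.07), the collagen gene Col11a2 (2.12, SE 0.06) and the netrin receptor gene Unc5d (2.07, SE 0.11) rose as well. Of 14866 genes 8530 (57.4%) passed edgeR's quasi-likelihood test, 4284 higher and 4246 lower. On the TPM scale the split moved, from 50.2% to 67.0% of calls being higher.

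Glycolysis genes had 24 of 27 members lower and 2 higher (24 and 2 adjusted over the list alone), including Aldoa (-2.09), Tpi1 (-2.02) and Aldoc (-1.68), with a camera adjusted p of 8.29e-25 and 0.0286 with an estimated correlation. Beta cell genes had 22 of 31 lower and 6 higher (22 and 6 adjusted over the list alone), including the granule gene Sytl4 (-1.40), the activin receptor gene Acvr1c (-1.25), G6pc2 (-0.73) and Ffar1 (-0.67), at 1.36e-07 and 0.00482 with an estimated correlation. Cholesterol genes had 24 of 25 lower and 0 higher (24 and 0 adjusted over the list alone; camera 1.08e-71). ATF4 genes had 31 of 36 lower and 2 higher (31 and 2 adjusted over the list alone; 4.44e-10), with Sesn2 at -0.76. Immediate early genes had 14 of 21 lower and 2 higher (14 and 2 adjusted over the list alone; 5.28e-09). These 5 of 9 camera calls held with an estimated correlation, the last 3 at 1.49e-05, 0.0231 and 0.00482. Interferon genes had 23 of 33 lower and 3 higher (25 and 4 adjusted over the list alone), with Oas2 at -1.98, camera adjusted p 0.00368 but adjusted p = 0.152 with an estimated correlation. Neuronal and exocytosis genes had 21 of 39 higher and 10 lower (21 and 10 adjusted over the list alone), with Chgb at 0.99 and Nefm at -1.69, camera adjusted p 0.00438 but adjusted p = 0.191 with an estimated correlation.

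Set against the DOX response of control cells, the miR-23b line's response was lower for Ak4 (log2 difference -6.14, SE 0.34), Mgl2 (-4.50, SE 0.40), the mucin gene Muc2 (-3.43, SE 0.51), Ldha (-3.31, SE 0.18) and the glucose transporter gene Slc2a2 (-2.53, SE 0.17), with n = 3 libraries per group. Mgl2 rose in control cells, to 7.80 CPM, and stood at 0.240 in the miR-23b line with DOX. Muc2 was near the detection limit there, at 0.171 CPM. The response was higher for Phlda3 (3.67, SE 0.40) and the protocadherin gene Pcdhb18 (2.02, SE 0.26). In all, 5583 genes (37.6%) passed edgeR's quasi-likelihood test of the difference, 2694 higher and 2889 lower, and on the TPM scale 69.9% of calls were higher in place of 48.3%.

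Of the lists, glycolysis genes had 23 of 27 members lower and 2 higher in this difference (23 and 2 adjusted over the list alone), including Bnip3 (-2.04), Tpi1 (-1.61) and Pfkl (-1.27), with a camera adjusted p of 3.87e-26. Of these 27 genes 10 carry a site for a miRNA of the cluster. Of all 13000 genes with a 3' UTR, 2274 carry a miR-23b-3p site, 2524 a miR-27b-3p site and 2787 a miR-24-3p site. The share with any of these sites was not computed, so the 10 are no sign of enrichment. Beta cell genes had 18 of 31 lower and 3 higher (18 and 3 adjusted over the list alone; 1.88e-15), including the insulin gene Ins1 (-1.28), Acvr1c (-1.48), Sytl4 (-1.12) and the cation channel gene Trpm5 (-1.42). Cholesterol genes had 20 lower and 1 higher (20 and 1 adjusted over the list alone; 2.48e-22). G1/S genes had 23 lower and 2 higher (23 and 2 adjusted over the list alone; 1.83e-09), among them Mcm4 (-0.46) and E2f8 (-0.48). Interferon genes had 15 lower and 3 higher (17 and 3 adjusted over the list alone; 4.17e-05). With an estimated correlation these 5 of 11 camera calls held, at 0.0295, 0.000249, 0.00556, 0.0108 and 0.0321.

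Calls that did not hold included G2/M genes, 24 of 39 lower and 0 higher (26 and 0 adjusted over the list alone), camera adjusted p 2.39e-05 but adjusted p = 0.189 with an estimated correlation. Among p53 targets 10 of 25 were higher and 7 lower (10 and 7 adjusted over the list alone), such as the CDK inhibitor gene Cdkn1a (0.89), Trp53inp1 (1.01), Zmat3 (0.76) and Sesn2 (-0.58). Their camera adjusted p was 0.0261 for higher, but adjusted p = 0.189 with an estimated correlation, and the list's median was -0.077 against a mean of 0.310. Neuronal genes had 20 of 39 higher and 5 lower (22 and 6 adjusted over the list alone), with Syt4 at 0.89 and Snap25 at 0.55, camera adjusted p 0.000404 but adjusted p = 0.104 with an estimated correlation. Islet progenitor genes had 11 of 27 lower and 5 higher (11 and 6 adjusted over the list alone), with Prom1 at -1.23 and Sox4 at 0.72, camera adjusted p 0.0149 but adjusted p = 0.152 with an estimated correlation. Epithelial genes had 5 of 10 lower and 0 higher (5 and 0 adjusted over the list alone), with Tjp1 at -0.44 and E-cadherin (Cdh1) at -1.12 (SE 0.21), camera adjusted p 0.0462 but adjusted p = 0.189 with an estimated correlation.

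Mesenchymal genes had 5 of 17 members higher and 0 lower (5 and 0 adjusted over the list alone), with vimentin (Vim) at 2.08 (SE 0.41) and Itgb1 at 0.27, and were not called by camera (adjusted p 0.188), though fry gave 0.000116. Vim stood at 1.91 ± 0.108 CPM in the miR-23b line with DOX and 0.513 ± 0.0735 in control cells with DOX. TGF-beta, activin and BMP genes had 12 of 35 higher and 5 lower (12 and 5 adjusted over the list alone), with Bambi at 0.83, Bmpr2 at 0.46 and Acvr1c lower, and were not called (camera adjusted p 0.43). Reported targets of miR-23b, miR-27b and miR-24 had 9 of 33 lower and 6 higher (9 and 6 adjusted over the list alone), with Notch1 at -1.01, Men1 at -0.38 and Ccng1 at 0.66. Camera gave this list an adjusted p of 0.211 and called it in 0 of the 12 comparisons, while fry gave 0.000642 here.

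In the miR-137 line, Ppargc1a, the coactivator of mitochondrial biogenesis, fell with 7 d DOX from 10.1 ± 0.848 to 2.63 ± 0.143 CPM (log2 fold change -1.95, SE 0.12, n = 3). The stearoyl-CoA desaturase gene Scd1 (-1.77, SE 0.05), Insig1 (-1.70, SE 0.04) and the adaptor gene Blnk (-1.94, SE 0.09) fell too. Pdzk1, a scaffold for membrane transporters (2.04, SE 0.12), Gcg (1.89, SE 0.08) and the kinase gene Dclk1 (1.33, SE 0.07) rose. Each of these also differed in the same direction from the response of control cells, but control cells moved the same way. With DOX their Insig1 went from 261 to 91.2 CPM, against 293 to 89.8 in this line. Their Scd1 went from 307 to 107, against 336 to 98.3. In control cells Ppargc1a went from 11.6 to 4.94, Blnk from 34.3 to 12.7, Pdzk1 from 2.11 to 5.5, Gcg from 16.7 to 43.4 and Dclk1 from 7.86 to 11.1. The fold changes above thus include a part shared with control cells. Of 14866 genes 6372 (42.9%) passed edgeR's quasi-likelihood test, 3126 higher and 3246 lower, and on the TPM scale 44.4% of calls were higher in place of 49.1%.

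Cholesterol genes again had 23 of 25 members lower and 0 higher (24 and 0 adjusted over the list alone; camera adjusted p 8.21e-71, and 1.68e-05 with an estimated correlation), the only 1 of 5 camera calls in the miR-137 line's own response that held. Reported miR-137 targets had 11 of 22 lower and 3 higher (11 and 3 adjusted over the list alone), with Akt2 at -0.41, Rora at -0.65, Fmnl2 at 0.38 and Jarid2 at 0.42, camera adjusted p 0.0342 but adjusted p = 0.0715 with an estimated correlation. ATF4 genes had 24 of 36 lower and 5 higher (25 and 5 adjusted over the list alone), camera adjusted p 7.95e-08 but adjusted p = 0.0715 with an estimated correlation. Hormone genes had 6 of 10 higher and 0 lower (6 and 0 adjusted over the list alone), camera adjusted p 0.0032 but adjusted p = 0.0723 with an estimated correlation. Neuronal genes had 21 of 39 higher and 8 lower (22 and 8 adjusted over the list alone), camera adjusted p 0.00256 but adjusted p = 0.168 with an estimated correlation.

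Several immediate early genes fell less under DOX in the miR-137 line than in control cells. The differences in response were 1.65 for Fos (SE 0.11, n = 3), 1.57 for Egr2 (SE 0.20), 1.49 for Fosb (SE 0.15) and 1.39 for Nr4a1 (SE 0.11). Fos stood at 86.7 ± 4.98 CPM with DOX in this line and at 29.2 ± 2.58 in control cells. Fosb still fell in this line, from 53.2 to 17.4 CPM, as did Egr2, from 13.7 to 6.80, and Nr4a1, from 67.8 to 41.0. Fxyd2, a regulator of the sodium pump, was also higher (1.62, SE 0.15). Mgl2 (-2.32, SE 0.31), Ppp1r16b (-1.22, SE 0.18), the interferon-induced Oas2 (-1.03, SE 0.20), the VIP receptor gene Vipr1 (-0.83, SE 0.10) and Trim66 (-0.82, SE 0.08) were lower. Mgl2 stood at 1.01 CPM without and 1.23 with DOX in this line, so its difference comes from the rise to 7.80 in control cells. Here 1588 genes (10.7%) passed edgeR's quasi-likelihood test, 877 higher and 711 lower. The higher share of calls, 55.2%, was 45.8% on the TPM scale and 66.5% with no filter on low counts, so the majority changed direction on the TPM scale.

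Immediate early and heat shock genes had 9 of 21 members higher and 1 lower in this difference (10 and 1 adjusted over the list alone; camera adjusted p 1.02e-17), including Ier2 (1.15) and Jun (0.63). Neuronal and exocytosis genes had 14 of 39 higher and 2 lower (16 and 2 adjusted over the list alone; 5.9e-07), with the granule peptide gene Vgf at 0.75, Rab3a at 0.48 and Syt13 at -0.24. Reported miR-137 targets had 6 of 22 lower and 1 higher (7 and 1 adjusted over the list alone; 0.00121), namely Akt2 at -0.34, Cdc42 at -0.30, Tcf4 at -0.23 and Rora at -0.39 among them. With an estimated correlation these 3 of 10 camera calls held, at 0.000147, 0.0277 and 0.0136. The G2/M list had 10 lower and 0 higher (18 and 0 adjusted over the list alone), 4.39e-08 but adjusted p = 0.132 with an estimated correlation. The G1/S list had 8 lower and 0 higher (17 and 2 adjusted over the list alone), 4.77e-06 but adjusted p = 0.0505 with an estimated correlation. Cholesterol genes had 7 lower and 1 higher (10 and 1 adjusted over the list alone), 8.09e-05 but adjusted p = 0.2 with an estimated correlation. Beta cell genes had 8 lower and 1 higher (9 and 3 adjusted over the list alone), 0.011 but adjusted p = 0.133 with an estimated correlation. Glycolysis genes had 5 higher and 1 lower (5 and 1 adjusted over the list alone), with Eno2 at 0.60, camera adjusted p 0.000593 but adjusted p = 0.593 with an estimated correlation, and fry gave 0.218.

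Between the miRNA lines, the DOX response of the miR-137 line exceeded that of the miR-23b line for Ak4 (6.49, SE 0.32, n = 3), Muc2 (3.61, SE 0.51), Ldha (3.54, SE 0.18), the lactate exporter gene Slc16a3 (2.49, SE 0.16) and Egr2 (2.36, SE 0.22). It was lower for Phlda3 (-2.74, SE 0.35) and Vwde (-2.23, SE 0.20). Glycolysis genes had 23 of 27 members higher and 1 lower (23 and 2 adjusted over the list alone; camera adjusted p 2.18e-38), immediate early genes 14 of 21 higher and 1 lower (14 and 1 adjusted over the list alone; 1.42e-11), and reported miR-137 targets 13 of 22 lower and 2 higher (13 and 3 adjusted over the list alone; 0.00161). Under an estimated correlation the adjusted p was 0.00736, 0.0012 and 0.00736, and 5 of 10 camera calls held, the others being the beta cell and cholesterol lists. In total 5240 genes (35.2%) passed edgeR's quasi-likelihood test, 2738 higher and 2502 lower, and the TPM scale gave 26.1% higher in place of 52.3%.

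**Figure D3:**
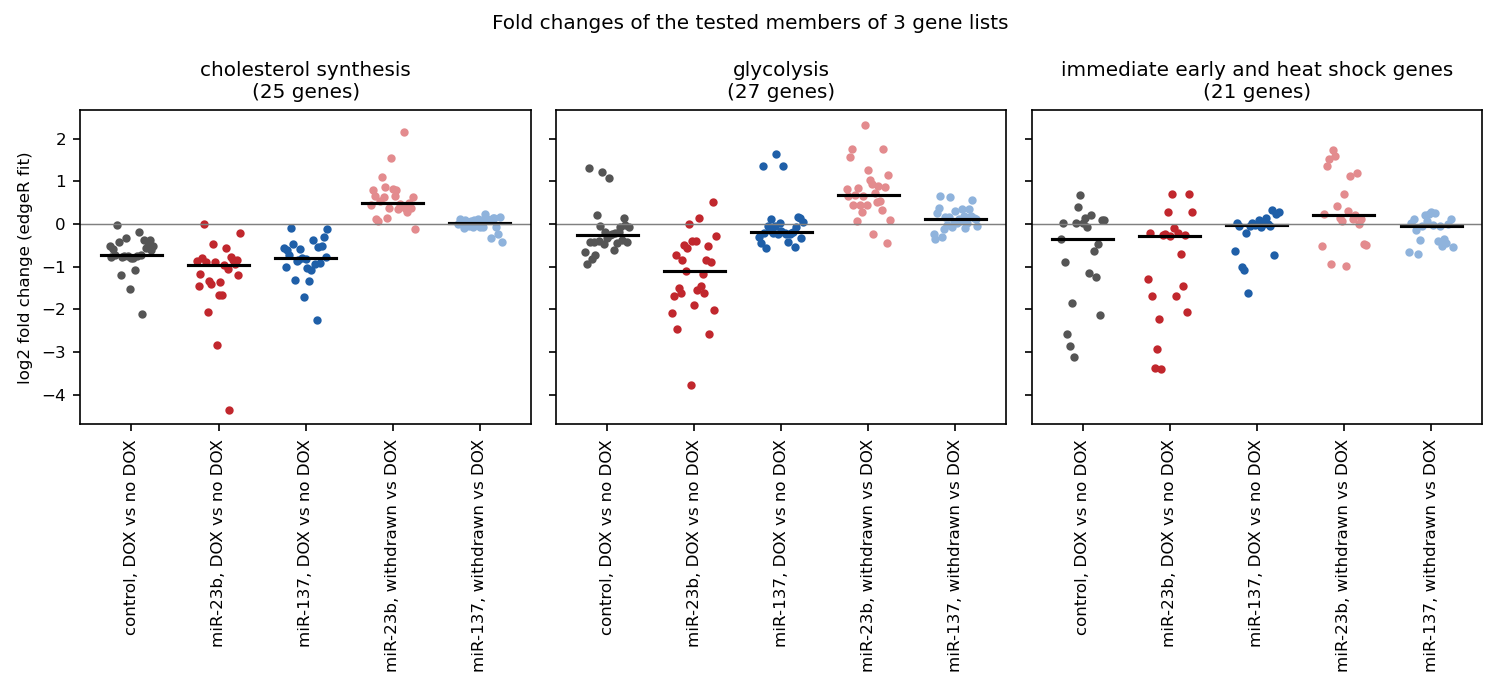
Log2 fold changes (7 d DOX against no DOX, and withdrawn against 7 d DOX) of the tested members of the glycolysis, cholesterol synthesis and immediate early lists in each line, each point a gene and each line a median. In the miR-23b line 24 of 27 glycolysis genes are called lower, against 18 in the control line.

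A miRNA lowers transcripts that carry its seed match, so sites in 3' UTRs were used as a readout of the induced miRNAs. Genes with a miR-137 site (1436 of 13000) had a difference in response to control cells that was lower by a coefficient of -0.0752 (SE 0.009) on the log2 scale than that of genes without. This was the second lowest among 10142 other 7-base words, behind only GCAATAA (-0.0837), which overlaps the miR-137 match AGCAATA by all but 1 base. In the miR-23b line, genes with a miR-23b-3p site (2274) gave -0.0606 (SE 0.0118), rank 2, those with a miR-27b-3p site (2524) -0.0543 (SE 0.0112), rank 5, and those with a miR-24-3p site (2787) -0.0465 (SE 0.011), rank 9. Each coefficient was negative in 3 of 3 induced libraries, but all had the same no DOX mean and control response subtracted. Their signs are thus not independent. In control cells with DOX the same coefficients were -0.0162, -0.0032, 0.0161 and 0.0198. The miR-137 sites gave 0.0014 in the miR-23b line's difference from control cells, and miR-23b-3p, miR-27b-3p and miR-24-3p sites gave -0.0065, -0.0003 and 0.003 in that of the miR-137 line. Without the covariates for UTR length and GC share the miR-24-3p coefficient was -0.002, the miR-27b-3p one -0.019 and the miR-23b-3p one -0.027.

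**Figure D4:**
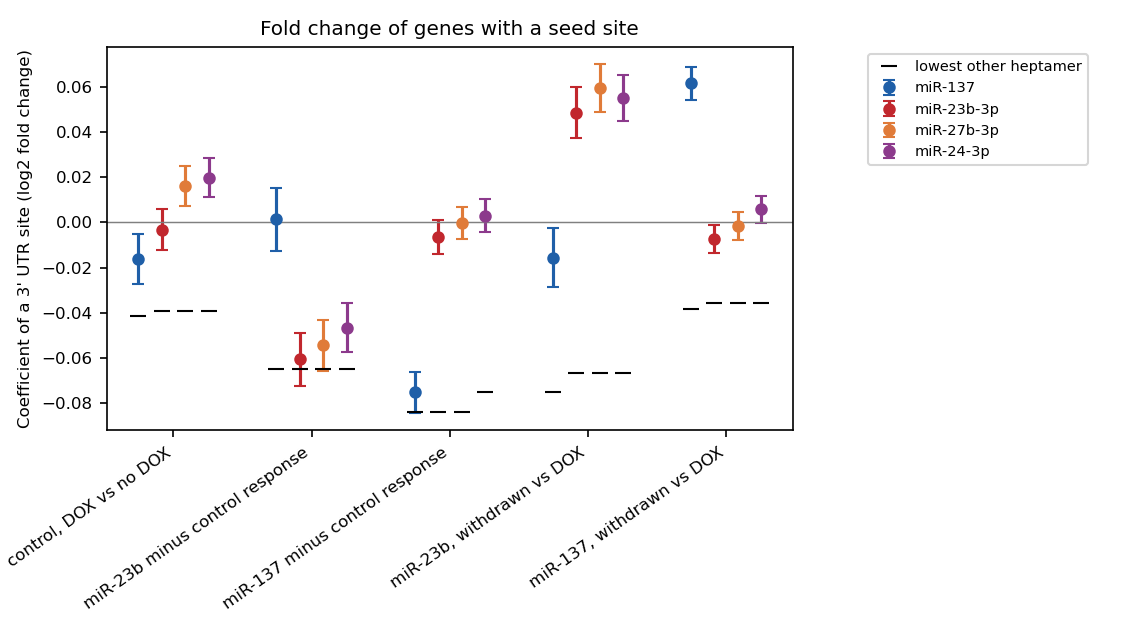
Coefficient of a site on the log2 fold change in 5 comparisons for the 4 miRNAs, with points as estimates, bars as SE and dashes as the lowest of the other 7-base words. In the difference from the control response the miR-137 coefficient is -0.0752 in the miR-137 line and the miR-24-3p coefficient -0.0465 in the miR-23b line.

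After withdrawal of DOX from the miR-23b line, Ak4 was higher than with 7 d DOX by a log2 of 5.88 (SE 0.32, n = 3), Slc2a2 by 2.34 (SE 0.13) and Ldha by 2.33 (SE 0.14). The withdrawn cultures were grown for 7 d longer, and the labels gave no withdrawn control culture. Time in culture may thus share in all differences between withdrawn and 7 d DOX cultures. The proline dehydrogenase gene Prodh2 rose by 2.02 (SE 0.09) to 21.2 CPM, past its 8.35 without DOX. Phlda3 (-3.55, SE 0.18) and Nxph4 (-2.13, SE 0.18) fell. Slc2a2 stood at 9.21 ± 0.60 CPM after withdrawal and 9.13 ± 0.594 without DOX. Ldha stood at 232 ± 62.1, below its 633 without DOX. In all 7760 genes (52.2%) passed edgeR's quasi-likelihood test, 3927 higher and 3833 lower, and on the TPM scale 27.8% of calls were higher in place of 50.6%. Of the 5583 genes with a response different from control cells, 4633 were called in the opposite direction on withdrawal and 41 in the same direction. The correlation across genes was -0.72, part of which comes from the shared 7 d DOX libraries, since simulated libraries without change gave -0.34. The simulated fold changes hold only noise, so the 2 correlations do not give the size of that part. The covariance was -0.189, against -0.0123 in the simulation. Genes are not independent replicates.

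Beta cell genes had 17 of 31 members higher after withdrawal and 5 lower (18 and 5 adjusted over the list alone; camera adjusted p 1.47e-07), including Ins1 (1.11) and Acvr1c (1.13). Cholesterol genes had 22 higher and 0 lower (22 and 0 adjusted over the list alone; 4.4e-24), and G1/S genes 27 higher and 3 lower (28 and 4 adjusted over the list alone; 8.61e-08). Neuronal genes had 29 lower and 4 higher (29 and 4 adjusted over the list alone; 8.05e-09), with Chgb at -0.83. With an estimated correlation the adjusted p was 0.00701, 0.00701, 0.0225 and 0.0106, and 6 of 9 camera calls held, the others being immediate early genes (0.0286) and p53 targets (0.0427). Glycolysis genes had 22 higher and 2 lower (22 and 2 adjusted over the list alone), 5.1e-14 but adjusted p = 0.0955 with an estimated correlation. On withdrawal, with UTR length and GC share as covariates, the site coefficients were 0.0485 for miR-23b-3p (SE 0.0111), 0.0593 for miR-27b-3p (SE 0.0105) and 0.0549 for miR-24-3p (SE 0.0103). Unadjusted medians with and without a site were 0.0099 and -0.0036 for miR-23b-3p, and 0.0138 and -0.0041 for miR-27b-3p. For miR-24-3p they were -0.0081 and 0.0002, so its site genes did not lie higher before adjustment.

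In the miR-137 line, the glutathione peroxidase gene Gpx2 was higher after withdrawal than with 7 d DOX by a log2 of 1.56 (SE 0.16, n = 3), Tcim by 1.05 (SE 0.14), the clock gene Ciart by 0.96 (SE 0.10) and the ATF4 target Trib3 by 0.89 (SE 0.07). In the miR-23b line Gpx2 also went from 1.62 to 5.88 CPM, Tcim from 4.41 to 8.42, Ciart from 3.88 to 7.75 and Trib3 from 23 to 24.7. Longer culture cannot be told apart from removal of DOX here either. Ddit4l (-1.54, SE 0.13), Gpr179 (-1.29, SE 0.14), Dclk1 (-1.18, SE 0.07), the synaptic gene C1ql3 (-1.12, SE 0.07) and Fxyd2 (-1.10, SE 0.09) fell. Dclk1 returned to 10.1 ± 0.240 CPM, against 9.13 ± 0.298 without DOX. The mitochondrial gene mt-Nd6 rose by 0.92 (SE 0.31; edgeR adjusted p 0.0213), a call that DESeq2 did not make (adjusted p 0.207, and 0.0177 to 0.0224 under the other alternatives). Here 4386 genes (29.5%) passed edgeR's quasi-likelihood test, 2185 higher and 2201 lower, with 24 higher and 110 lower among those of at least 2-fold, and on the TPM scale 41.4% of calls were higher in place of 49.8%. Of the 1588 genes that differed from the control response, 1195 were called in the opposite direction on withdrawal and 20 in the same direction. The correlation across genes was -0.464, against -0.354 in simulated libraries without change, whose fold changes hold only noise. The covariance was -0.0456, against -0.0119 in the simulation.

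Neuronal genes had 24 of 39 members lower and 3 higher after withdrawal (25 and 3 adjusted over the list alone; camera adjusted p 3.68e-12), with Vgf at -1.09 and Rab3a at -0.49. G2/M genes had 29 higher and 0 lower (30 and 0 adjusted over the list alone; 2.78e-13), G1/S genes 22 higher and 0 lower (23 and 0 adjusted over the list alone; 8.4e-09) and ATF4 genes 22 higher and 2 lower (23 and 4 adjusted over the list alone; 2.95e-07). Reported miR-137 targets had 8 of 22 higher and 3 lower (8 and 3 adjusted over the list alone; 0.0125), with Akt2 at 0.40, Rora at 0.52 and Fmnl2 at -0.31. These 5 of 6 camera calls held with an estimated correlation, at 0.00756, 0.0386, 0.023, 0.0484 and 0.0385. ER stress genes had 15 higher and 0 lower (17 and 0 adjusted over the list alone), 2.95e-07 but adjusted p = 0.0537 with an estimated correlation. Genes with miR-137 sites moved up relative to genes without by a coefficient of 0.0614 (SE 0.0074).

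Cells withdrawn from DOX still differed from cells never given it. In the miR-23b line Pdzk1 was higher by a log2 of 2.39 (SE 0.10, n = 3), Gpx2 by 1.68 (SE 0.17) and Sct by 1.65 (SE 0.08), while Blnk (-2.47, SE 0.11), the IGF-binding protein gene Igfbp2 (-2.03, SE 0.10) and Nr4a1 (-1.95, SE 0.09) were lower. Cholesterol genes had 23 of 25 lower and 0 higher (23 and 0 adjusted over the list alone; camera adjusted p 4.18e-51, and 8.94e-05 with an estimated correlation). Glycolysis genes had 19 of 27 lower and 3 higher (19 and 3 adjusted over the list alone), with Aldoa at -1.27, camera adjusted p 4.98e-11 but adjusted p = 0.218 with an estimated correlation. In all 5916 genes (39.8%) passed edgeR's quasi-likelihood test, 2858 higher and 3058 lower (48.3% higher, and 43.4% on the TPM scale), and 2 of 11 camera calls held with an estimated correlation. The withdrawn cultures were grown for 7 d longer than those without DOX.

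In the miR-137 line, withdrawn cells had higher Gpx2 (2.15, SE 0.18, n = 3), Pdzk1 (2.10, SE 0.12), Gcg (1.86, SE 0.08), Meltf (1.78, SE 0.14) and Pdyn (1.64, SE 0.09) than cells without DOX. Blnk (-2.13, SE 0.09), D5Ertd615e (-1.97, SE 0.17), Scd1 (-1.84, SE 0.05) and Chchd10 (-1.71, SE 0.10) were lower. Cholesterol genes had 24 of 25 lower and 0 higher (24 and 0 adjusted over the list alone; camera adjusted p 1.32e-74, and 1.95e-05 with an estimated correlation), the only 1 of 6 camera calls that held. ER stress genes had 16 of 21 higher and 2 lower (16 and 2 adjusted over the list alone), with Pdia4 at 0.70 and Hspa5 at 0.39, camera adjusted p 4.92e-09 but adjusted p = 0.0752 with an estimated correlation. G2/M genes had 32 of 39 higher and 2 lower (33 and 2 adjusted over the list alone), camera adjusted p 6.71e-10 but adjusted p = 0.141 with an estimated correlation. In all 6450 genes (43.4%) passed edgeR's quasi-likelihood test, 3217 higher and 3233 lower, and the TPM scale gave 39.5% higher in place of 49.9%.

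Both withdrawn lines resembled control cells under DOX, with which they share no library. Of the 5624 genes called in the control response, 4060 were called in the same direction in the withdrawn miR-137 line and 41 in the opposite one, where independent calls would share 596 higher and 624 lower. The correlation across genes was 0.664, and 0.562 for the withdrawn miR-23b line (3528 in the same direction, 96 opposite). Simulated libraries without change gave 0.001 and 0.00367, values near 0 that follow from drawing each library independently. The simulation held no batch shared by the no DOX cultures, so it cannot tell a lasting DOX response from such a batch. The control response also correlated with that of the miR-137 line under DOX at 0.637 (3622 in the same direction, 102 opposite) and with that of the miR-23b line at 0.435 (3386 and 625). Genes are not independent replicates, and 9 such pairs of comparisons were computed.

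Without DOX the miRNA lines were close to the control line. Fxyd2 was higher in the miR-23b line (log2 fold change 1.01, SE 0.08, n = 3), as was the axonemal gene Dnah6 (0.88, SE 0.10), and Muc2 (-1.11, SE 0.20), Plekhg4 (-0.72, SE 0.13) and the incretin gene Gip (-0.65, SE 0.09) were lower. Cholesterol genes had 19 of 25 higher and 0 lower (23 and 0 adjusted over the list alone; camera adjusted p 8.9e-32), with Lss at 0.29. Interferon genes had 4 of 33 lower and 0 higher (9 and 1 adjusted over the list alone; 4.26e-05), with the MHC class I subunit gene B2m at -0.46 and the RNA sensor gene Dhx58 at -0.56. These 2 of 11 camera calls held with an estimated correlation, at 0.00198 and 0.0366. In all 947 genes (6.4%) passed edgeR's quasi-likelihood test, 533 higher and 414 lower. Leaving out any 1 of the 6 libraries lowered the count, to between 465 and 676. It was 479 without control no DOX replicate 2, and 465, 589 and 624 without replicates 1, 2 and 3 of the miR-23b line. On the TPM scale 2.85% of genes passed in limma's test, with 33.7% of calls higher in place of 56.3%, and with no filter on low counts 47.4% were higher.

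The miR-137 line without DOX also had higher Fxyd2 than control cells (0.97, SE 0.08, n = 3), with the secreted glycoprotein gene Cthrc1 (0.73, SE 0.13) and the synaptic scaffold gene Homer2 (0.67, SE 0.08). The protease gene Pappa2 (-0.70, SE 0.07), Epop (-0.68, SE 0.15) and Sectm1a (-0.62, SE 0.11) were lower. March11 was lower by edgeR (-0.48, SE 0.12, adjusted p 0.0204) but not by DESeq2 (adjusted p 0.0611, and 0.0179 to 0.0205 under the other alternatives). Cholesterol genes had 10 of 25 higher and 0 lower (15 and 0 adjusted over the list alone; camera adjusted p 4.64e-15), and interferon genes 3 of 33 lower and 0 higher (6 and 1 adjusted over the list alone; 6.39e-07), with B2m at -0.41 and Tap1 at -0.26. These 2 of 5 camera calls held with an estimated correlation, at 0.0307 and 0.0256. In all 402 genes (2.7%) passed edgeR's quasi-likelihood test, 281 higher and 121 lower. This count was 170 and 192 without control no DOX replicates 2 and 3, 185 and 253 without replicates 1 and 2 of the miR-137 line, and on the TPM scale 1.02% of genes passed in limma's test, with 62.5% of calls higher in place of 69.9%.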

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

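The differences between the lines' DOX responses were tested by interaction terms planned before the data were examined. Of the tests below, only that of sites as the whole cause of the glycolysis change was chosen after the results were seen. The readings of the sites and splits tests depart from the rules fixed beforehand, as stated with each.

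Because the DOX response of the miR-23b line differed from that of the control line, 5583 genes came up for a closer look as a count, with these named genes. The log2 differences were 3.67 for Phlda3, 2.02 for Pcdhb18, -6.14 for Ak4, -4.50 for Mgl2, -3.43 for Muc2, -3.31 for Ldha and -2.53 for Slc2a2. By camera with an estimated correlation, the lists that differed were beta cell identity (adjusted p 0.000249), cholesterol synthesis (0.00556), G1/S (0.0108), glycolysis (0.0295) and interferon response (0.0321).

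The DOX response of the miR-137 line differed from that of the control line in 1588 genes. The named ones were Fos (log2 difference 1.65), Fxyd2 (1.62), Egr2 (1.57), Fosb (1.49), Nr4a1 (1.39), Mgl2 (-2.32), Ppp1r16b (-1.22), Oas2 (-1.03), Vipr1 (-0.83) and Trim66 (-0.82). The lists that differed by camera with an estimated correlation were immediate early and heat shock genes (adjusted p 0.000147), reported miR-137 targets (0.0136) and neuronal and exocytosis genes (0.0277).

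The responses of the miRNA lines differed from each other in 5240 genes, the miR-137 line minus the miR-23b line giving 6.49 for Ak4, 3.61 for Muc2, 3.54 for Ldha, 2.49 for Slc16a3, 2.36 for Egr2, -2.74 for Phlda3 and -2.23 for Vwde. The lists that differed by camera with an estimated correlation were beta cell identity (adjusted p 0.0012), immediate early genes (0.0012), glycolysis (0.00736), reported miR-137 targets (0.00736) and cholesterol synthesis (0.017).

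The glycolysis genes responded to DOX with lower values in the miR-23b line than in control cells, and direct miRNA sites in them were weighed against technical and other biological explanations. Scored sites as the whole cause were argued against. The 17 members without a scored site still had a median log2 difference in response of -0.85 (SD 0.87). The 10 with a scored site had -1.37 (SD 0.75). Shorter sites, and sites outside the longest annotated UTR, were not scored, so direct targeting through them stays open. The rule fixed beforehand asked only for a median lower by a set amount in genes with a site, which the difference of -0.53 met. A permutation test that this rule did not hold gave a 2-sided p of 0.122 (100000 resamples). Whether the scored sites added to the difference thus cannot be told apart from chance. A lower oxygen-response programme is a candidate explanation that the data left standing, as 23 hypoxia-inducible genes outside the list had a median of -0.37 (SD 0.66) in the same difference, 16 called lower and 4 higher. Density, medium or oxygen of that group's plates stays open, because 0 sample labels give them.

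Other splits of the same libraries were tested for each count of genes. For the differences between responses, 100 splits were drawn. The miR-23b against control count of 5583 was reached by 5 of 100 splits, the real one included, with a highest other of 6408, and that of the miR-137 line (1588) by 10 of 100, with a highest other of 7707. For the 5240 genes between the miRNA lines, 3 of 100 splits were as large, with a highest other of 6122. The 4, 9 and 2 other splits that were as large all kept the real groups of 1 line intact, so that line's own DOX response set their counts. These tallies follow from how many such splits were drawn, and for none of the 3 counts do they decide whether chance can be excluded. Splits that kept neither line intact gave at most 0 genes by edgeR. The 7707 genes, several times the real 1588, came from the split that exchanged DOX and no DOX in 1 line and point to the response that both lines share.

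Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. In each of the 9 such comparisons only 1 split, the real one, gave as many genes. The real counts were 5624 (highest other split 16), 8530, 6372, 7760, 4386, 5916, 6450 and 402 (highest other 0 for each of these 7) and 947 (highest other 2).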

How the results depend on the processing

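Of the alternatives, only limma on log2(TPM + 1) was chosen after the results were seen. The count table for the whole series held the same values as the files per sample, so it gave no alternative.

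Counts of genes are given here as percentages of the 14866 genes tested. All 12 stayed within 1.5 times their value with size factors in place of TMM, with no filter on low counts, with DESeq2 (30.9% in place of 37.8% for control cells with DOX) and with a fit of only the groups compared. On the TPM scale 10 of 12 did. The others went from 6.4% to 2.85% (miR-23b line without DOX against control) and from 2.7% to 1.02% (miR-137 line), and the cause was not tested. On the TPM scale the median gene lay at most 0.083 from 0 in log2 (-0.083, against -0.001 with TMM, for the miR-137 minus miR-23b response).

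A required fold of at least 2 left fewer genes by its construction. With 7 d DOX against no DOX it left 2.81% in control cells, 6.46% in the miR-23b line and 3.07% in the miR-137 line. Differences between responses kept 3.69% (miR-23b minus control), 0.632% (miR-137 minus control) and 3.43% (miR-137 minus miR-23b). Withdrawal against 7 d DOX kept 4.46% and 0.901%, withdrawal against no DOX 3.27% and 3.03%, and the lines without DOX 0.135% and 0.074%, in each case for the miR-23b and miR-137 lines. Of these genes, in the same order, 52.3%, 42.4%, 50.9%, 36.7%, 52.1%, 61.0%, 44.2%, 17.9%, 33.3%, 31.0%, 55.0% and 63.6% were higher.

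Leaving out 1 library at a time gave 32.1% to 34.9%, 51.9% to 54.3% and 37.4% to 39.2% for DOX in the control, miR-23b and miR-137 lines. The differences between responses gave 34.5% to 36.1%, 8.51% to 10.9% and 31.3% to 33.9%. Withdrawal against DOX gave 46.5% to 49.7% and 23.6% to 28.6%, and against no DOX 33.4% to 36.9% and 37.0% to 40.2%. The miRNA lines without DOX against control gave 3.13% to 4.55% and 1.14% to 1.98%. The former count was 479 without control no DOX replicate 2, and 465, 589 and 624 without miR-23b no DOX replicates 1, 2 and 3. The latter was 170 and 192 without control no DOX replicates 2 and 3, and 185 and 253 without miR-137 no DOX replicates 1 and 2. Fewer libraries leave fewer degrees of freedom by construction, and other causes were not tested.

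The labels give replicate numbers no meaning, so the samples were not treated as paired. Over 84 pairs of libraries with the same number in different groups the median correlation of residuals was 0.027 (-0.066 to 0.183, 3 above 0.1), against -0.014 for different numbers. Yet 20 of 24 libraries correlated best with libraries of their own number, where about 1 in 3 would by chance. With all libraries thinned to 1 depth, replicate 1 also had the most genes detected in every group. Libraries of the same number thus appear linked, though the correlations are small, and the main fit leaves this link out. A block for replicate number kept all 12 counts within 1.5 times and raised each of them. Control cells with DOX went from 37.8% to 38.6%, and the miR-137 line without DOX against control from 2.7% to 3.67%.

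Each site coefficient stayed negative under every setting run. With 8-base sites the miR-137, miR-23b-3p, miR-27b-3p and miR-24-3p coefficients were -0.099, -0.092, -0.106 and -0.058. Without UTR covariates they were -0.088, -0.027, -0.019 and -0.002. In the line's own response the miR-137 coefficient was -0.091, that of miR-27b-3p -0.038 and that of miR-24-3p -0.027. With genes at 5 CPM or more, miR-137 gave -0.065 and miR-27b-3p -0.062. The cause of these changes was not tested. Leaving out 1 library gave -0.079 to -0.070, -0.064 to -0.057, -0.058 to -0.050 and -0.051 to -0.042.

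Of 150 genes selected for naming, DESeq2 ended 2 calls (mt-Nd6 and March11), and size factors and the block none. Of 67 list results, an estimated correlation ended 28 and kept 39, fry ended 1 and added 3, and the block changed 0. Over all 21 lists in 12 comparisons the block changed 5 camera calls. It added ER stress genes in the miR-137 line with DOX (adjusted p 0.0557 to 0.0352), in the miR-23b minus control response (0.0526 to 0.035), in the miR-23b line withdrawn against DOX (0.0668 to 0.048) and in the miR-137 line without DOX (0.075 to 0.0492). It ended immediate early genes in the miR-137 line withdrawn against no DOX (0.0402 to 0.0519). At this depth a count of 0 over a group allows up to 0.0588 CPM, which limits statements on miRNA loci outside the induced lines. Mir137 had 0 counts in every library while Gm26871 had 7182 in the miR-137 line with DOX, and how reads were assigned where the 2 overlap was not tested.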

Other observations

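The tests below of continuing induction, longer culture as a whole cause, library depth, cells of another type and unspliced reads were chosen after the results were seen.

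Levels of 3 peptide hormone genes are given here (n = 3 libraries per group). Sct stood at 12.3 ± 0.618 CPM in the miR-23b line without DOX, 69.7 ± 4.10 with it and 38.7 ± 1.98 after withdrawal. Gip stood at 31.9 ± 1.04 in the miR-137 line with DOX and 14.9 ± 1.40 without, against 13.4 ± 0.579 and 11.9 ± 0.846 in the miR-23b line and 26.6 ± 2.11 and 18.6 ± 1.17 in the control line. Ins1 stood at 1064 ± 11.9 CPM in the miR-23b line with DOX and at 2497 ± 91.5 and 2567 ± 71.0 in the control and miR-137 lines with DOX, above their 1873 ± 52.8 and 2066 ± 129 without DOX.

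Further values of 2 stress lists belong to the withdrawn miR-23b line. ATF4 and mitochondrial stress genes were lower in withdrawn than in untreated miR-23b cells, 28 of 36 lower and 2 higher. Adjusted over the list alone 30 were lower and 2 higher, with a camera adjusted p of 2.39e-12, and 0.0159 with an estimated correlation. Among p53 targets, withdrawal of DOX from the miR-23b line lowered 12 of 25 and raised 9 (12 and 9 adjusted over the list alone; camera adjusted p 0.000261, and 0.0427 with an estimated correlation), with a list median of -0.019 against a mean of -0.449. Cdkn1a stood at 115 ± 4.83 CPM in that line without DOX, 218 ± 6.29 with it and 95.7 ± 0.794 after withdrawal.

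Withdrawn cultures still differed from cultures without DOX. Continuing transcription of the induced loci at harvest was argued against. The 3 cluster loci summed to at most 0.524 CPM in a withdrawn library, against up to 1.33 without DOX and at least 236 with it. Gm26871 reached at most 3.48, against up to 4.58 and at least 121. Mature miRNAs were not measured, so their persistence stays open. In withdrawn against no DOX, miR-137 sites gave a coefficient of -0.0301 (SE 0.0108) in the miR-137 line and -0.0304 (SE 0.0115) in the miR-23b line. In the latter, miR-23b-3p, miR-27b-3p and miR-24-3p sites gave -0.0153, 0.0212 and 0.0282. Longer culture as the whole cause was argued against, because the change in withdrawn cells correlated with the control line's response to 7 d DOX at 0.562 or more across genes, at equal culture time. A lasting effect of DOX may be part of it, but 0 libraries of untreated cultures kept as long were made to tell it apart from time in culture. A batch shared by the no DOX cultures cannot be told apart either, since 0 labels give a date, plate or run.

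More genes were detected in the control line with DOX than elsewhere. Depth was excluded, since after thinning all libraries to 1 depth its lowest library still had 20285 genes, against at most 19705 in the other 21. Cells of another type cannot be told apart as a source, because the markers of 3 of 4 lists lay near the floor. For endothelium, Plvap stood at 8.06 CPM against a mean of 7.59 in all libraries, a list ratio of 1.15. The highest ratio over 4 marker lists was 1.5, for fibroblasts, whose most abundant gene Col1a1 stood at 3.88 CPM against a mean of 2.90 in all libraries. Mgl2, a lectin gene of macrophages, stood at 7.80 CPM there and at most 1.34 in the other groups. Unspliced or genomic reads cannot be told apart as a source, as reads outside genes per 100 gene reads were 16.8 in its lowest library and 19.9 in its highest, against 15.4 to 19 in the others. Its mean of 18.4 was the highest of the 8 groups, though the miR-23b line with DOX, at 18.3, had 19448 genes after thinning against its 20364. No biological explanation was tested.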
